A study of Mus musculus with 4 samples.

How the data were processed

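The series measured RNA in single cells of mouse kidney. The cells were NKp46-positive NK1.1-positive innate lymphoid cells (ILC), a group of lymphocytes without rearranged antigen receptors that includes natural killer (NK) cells and type 1 ILC (ILC1). Per the labels, they were sorted as live CD45-positive cells negative for the lineage markers CD3, CD5, CD19 and Ly6g and unstained by a CD45.2 antibody given intravenously, which leaves out cells inside blood vessels. The sort purity was above 98%, per the labels' protocols. The mice carried a RORγt fate map (FM), a genetic tag that stays on in a cell and its progeny once the transcription factor RORγt (gene Rorc) has been expressed. FM-negative and FM-positive cells were collected from 12 untreated mice and from 8 mice given poly(I:C), a synthetic double-stranded RNA that triggers type I interferon. The labels give no dose or time of poly(I:C).

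Libraries were made with the Chromium Next GEM Single Cell 5' v2 kit and sequenced on a NextSeq 2000, per the labels' protocols. The authors deposited 4 matrices of unique molecular identifier (UMI) counts per gene and cell barcode, 1 per group, with 32285 genes each, per the file headers. Cell Ranger 5.0.0 and the genome build mm10 are named in the submitters' processing notes. The matrices are whole-number counts from the filtered output, not normalised. The annotation release, the treatment of intronic reads and any further filter are not given in the sources used here. Mice of a group were not told apart by the labels, so each group is 1 library and 1 sample. There is therefore no replicate, no test and no p-value anywhere, and every difference compares 4 libraries, not conditions.

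From these counts, barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. This left out 63 barcodes of the untreated FM-negative, 90 of the untreated FM-positive, 186 of the poly(I:C) FM-negative and 18 of the poly(I:C) FM-positive library. Doublets were called per library with Scrublet in scanpy 1.11.5, with an expected share of 0.8% per 1000 cells. It removed 4, 10, 0 and 7 barcodes in the same order. Marking 0 of 7685 cells in the largest library, where 6.15% were expected, means that the caller did not work there, so doublets remain among the cells of that library. In untreated FM-negative it marked 0.153% where 2.09% were expected, so doublets may remain there too. In untreated FM-positive it marked 1.68% where 0.476% were expected. An added alternative, chosen after seeing the data, removed the expected share of highest scores in each library.

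Cells of the 4 libraries were clustered together on 2000 variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 0.6 (leidenalg 0.10.2). Mitochondrial and ribosomal protein genes were left out of the clustering genes. So were the members of the interferon-stimulated, cell cycle, immediate-early and heat-shock, and sex-linked lists described below. Other genes of these responses were not left out, and some, such as Cxcl10, Egr2 and Hells, were among the leading genes of clusters. The clusters are therefore not independent of the interferon response or the cell cycle. Clusters were named only from marker sets for NK cells, ILC1, ILC2, ILC3, T cells, B cells, myeloid cells, neutrophils, mast cells or basophils, kidney epithelium, endothelium and erythroid cells. A class other than NK cells or ILC1 needed at least 3 markers at 10 CPM or more and at least 4-fold above the other cells. Every other cluster was set to NK cells or ILC1, whichever marker set had the higher mean log2 level. A name also needed at least 3 detected markers, at 10 CPM or more. Clusters 4 and 5 (NK-like) and 8 (ILC1-like) had 0 markers of their class among their 10 leading genes. A cluster stayed unnamed when its 10 leading genes held more markers of another class, or when it had a low UMI count and none of its markers among them. Gzma and Prf1 are among the 10 NK markers, and Il7r, Cxcr6 and Tmem176a among the 10 ILC1 markers, so these genes help to name the classes. The genes that lead a cluster of a class are not named as differences within that same class, although gene lists compared within a class hold some of them. Some genes named within ILC1-like cells lead NK-like clusters (Klra4, Sell, Gzmc, Mki67, Eomes and Il18r1).

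UMIs were summed over the retained cells of a library, or of 1 class in a library, and given as CPM, the UMIs of a gene scaled to the same total in every library with exact Poisson 95% intervals. Folds carry an exact conditional binomial 95% interval, and shares of cells carry a Clopper-Pearson 95% interval. These intervals cover counting error only, not the variation between mice, sorts or library preparations. The intervals of CPM and folds treat UMIs as independent, so they also leave out the variation between cells. They are too narrow where few cells hold most UMIs of a gene. In untreated FM-positive, for example, 2635 Miox UMIs lay in 42 kidney epithelial-like cells. A fold against a count of 0 was computed against a floor of 3 counts in that library. Log2 ratios used a pseudocount of 1 CPM. Within a class, groups with fewer than 50 cells were not compared. Shares of cells with a UMI were also computed after thinning each cell to 2000 UMIs, which leaves out 48, 17, 136 and 7 shallower cells in the order above.

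The 15 gene lists covered interferon-stimulated genes, MHC class I antigen presentation, cytotoxic effector genes, cytokines and chemokines, NK maturation and circulation, tissue residency, ILC3-associated genes, cytokine receptors and feedback, NK receptors, inhibitory and activation receptors, cell cycle, immediate-early and heat-shock genes, glycolysis, oxidative phosphorylation and sex-linked genes. For each list, members with at least 5 CPM in the higher library entered the median log2 ratio, which is given with a binomial 95% interval over members. Its percentile among 10000 random lists of the same size and matched expression describes these libraries and is no test. A member was counted as higher or lower when its ratio of CPM + 1 was at least 1.5-fold. A member at a low level can therefore count as within 1.5-fold although its ratio of CPM is larger. The lists share genes with the markers, so list medians, markers and class shares are not separate evidence. Cd200r1, Itga1, Il7r, Cxcr6, Rora, Inpp4b and Ckb are both ILC1 markers and tissue residency members. Eomes, Itgam, Klra8, Klra4, Klra9, S1pr5, Cma1 and Irf8 are both NK markers and members of the NK maturation and circulation list. The groups, the lists, the markers, the comparisons, the rule for naming genes and the alternatives, apart from the added ones, were set before the data were examined.

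For whole libraries, the rule took genes with at least 20 CPM and a UMI in at least 5% of cells of the higher library. It left out mitochondrial, ribosomal protein, haemoglobin, sex-linked, immunoglobulin and T cell receptor segment genes and unnamed gene models. It then took the 12 highest and 12 lowest genes by log2 ratio with a pseudocount of 5 CPM. Within a class it took 6 in each direction, and for each list up to 4 members. Genes of the sort and the fate map (Ncr1, Klrb1c, Ptprc, Rorc, Cd3e, Cd5, Cd19 and Ly6g) were always included. Members of the Klra and H2 families are near-identical to each other, so their counts can be split between copies and are uncertain. Coordinates are those of the gene in the GENCODE mouse annotation for GRCm38, the same assembly as mm10, in which 32158 of the 32285 gene identifiers (99.6%) were found. All values printed are for whole genes, not for single transcripts.

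Scaling matters for the treatment comparisons. Median-of-ratios size factors moved the median of all genes by 0.27 (log2) for FM-negative and 0.30 for FM-positive whole libraries, and by 0.17 and 0.22 within ILC1-like cells. The shift was 0.15 for the treatment comparison within NK-like cells and -0.12 for the untreated comparison of FM-positive with FM-negative. List medians are therefore also given relative to the median of all genes. Other alternatives were no cell filter for class shares, no cell filter and no doublet removal together for list medians and named genes, at most 5% mitochondrial UMIs, doublets kept, Leiden resolutions of 0.3 and 1, the left-out genes kept, treatments clustered apart, thinning before clustering, equal weight per cell, a pseudocount of 5 CPM, no minimum for list members, and only NK-like and ILC1-like cells.

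The code was tested on simulated Poisson counts of summed UMIs with 200 changed genes per comparison. The intervals rest on the same model, so their coverage here checks the code and not the variation of UMIs between cells. For the treatment comparison in FM-negative, the median recovered log2 ratio was 1.97 for a true value of 2 and 0.98 for a true value of 1 among 6468 genes, and 95.2% of the intervals of unchanged genes held the truth. For the untreated comparison of FM-positive with FM-negative, these were 1.91 and 0.93 among 6468 genes, with 95.2%. Of the intervals of the 50 genes with a true value of 2 in that comparison, 90% held the truth. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.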

Results

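The data comprised 1 library for each of 4 groups of kidney NKp46-positive NK1.1-positive ILC, FM-negative or FM-positive cells from untreated or poly(I:C)-treated mice. The untreated FM-negative library held 2609 retained cells and 13315977 UMIs, and the untreated FM-positive library 585 cells and 3239785 UMIs. After poly(I:C) there were 7685 FM-negative cells with 101746436 UMIs and 989 FM-positive cells with 9776315 UMIs. The median depth per cell was 4704 and 4913 UMIs in the untreated libraries and 10547 and 8214 UMIs after poly(I:C), in the same order. There were no replicates, so no difference below could be set against a spread between samples, and all intervals are counting intervals.

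Transcripts of the sort were present in every library. Ncr1, which encodes NKp46 (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164, plus strand), stood at 1494 against 1581 CPM in untreated FM-positive against FM-negative cells and at 992 against 871 CPM after poly(I:C). Klrb1c, which encodes NK1.1, stood at 783 against 861 CPM and 708 against 672 CPM. Ptprc, which encodes CD45, stood at 1117 against 1333 CPM and 1197 against 1348 CPM, in the same order. The untreated differences in Ncr1 and Klrb1c turned round when only NK-like and ILC1-like cells were summed, with log2 ratios of 0.13 and 0.09. That in Klrb1c after poly(I:C) turned with another scaling, to -0.02. Cd19 had 0 UMIs in all 4 libraries, where a floor of 3 counts stands for 0.225, 0.926, 0.0295 and 0.307 CPM in the order untreated FM-negative, untreated FM-positive, poly(I:C) FM-negative and poly(I:C) FM-positive. Cd5 stayed at or below 0.409 CPM and Ly6g at or below 0.0688 CPM.

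Most untreated cells fell into ILC1-like clusters, and NK-like cells were a larger part of the FM-negative libraries. ILC1-like cells made up 72.8% (71.0 to 74.5) of untreated FM-negative and 81.7% (78.3 to 84.8) of untreated FM-positive cells. After poly(I:C) they made up 24.6% (23.6 to 25.5) and 58.2% (55.1 to 61.3). NK-like cells made up 21.5% (19.9 to 23.1) of untreated FM-negative and 2.74% (1.57 to 4.40) of untreated FM-positive cells, and 51.2% (50.1 to 52.3) and 17.8% (15.5 to 20.3) after poly(I:C). After thinning every cell before clustering, the NK-like shares were 25.1%, 7.04%, 71.2% and 33.9% in the order untreated FM-negative, untreated FM-positive, poly(I:C) FM-negative and poly(I:C) FM-positive.

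The classes were held by different clusters before and after treatment. Cluster 0 held 1775 of the 1899 untreated FM-negative ILC1-like cells, while cluster 2 held 1572 of the 1887 after poly(I:C). NK-like cells were mostly in cluster 6 in the untreated libraries and in clusters 1, 4 and 5 after poly(I:C), of which 4 and 5 were led by cell cycle genes. A further group, cluster 3, stayed unnamed because Cd3g and Cd3d were among its leading genes beside NK receptor genes, and it held 0.0767%, 0%, 14.6% and 8.59% of cells in the same order as the thinned shares. Its nearest class was NK cells, with Eomes at 169, Itgam at 140 and Prf1 at 993 CPM, against 214, 224 and 1502 CPM in cluster 1. NK-like shares after poly(I:C) were therefore larger when cluster 3 was counted as NK-like, as given under the processing below. The share without any name, cluster 3 included, was 1.26%, 2.05%, 17.7% and 10.0%. The sort set which cells entered each library, and the poly(I:C) libraries were deeper, so that these shares are those of sorted cells.

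**Figure D1:**
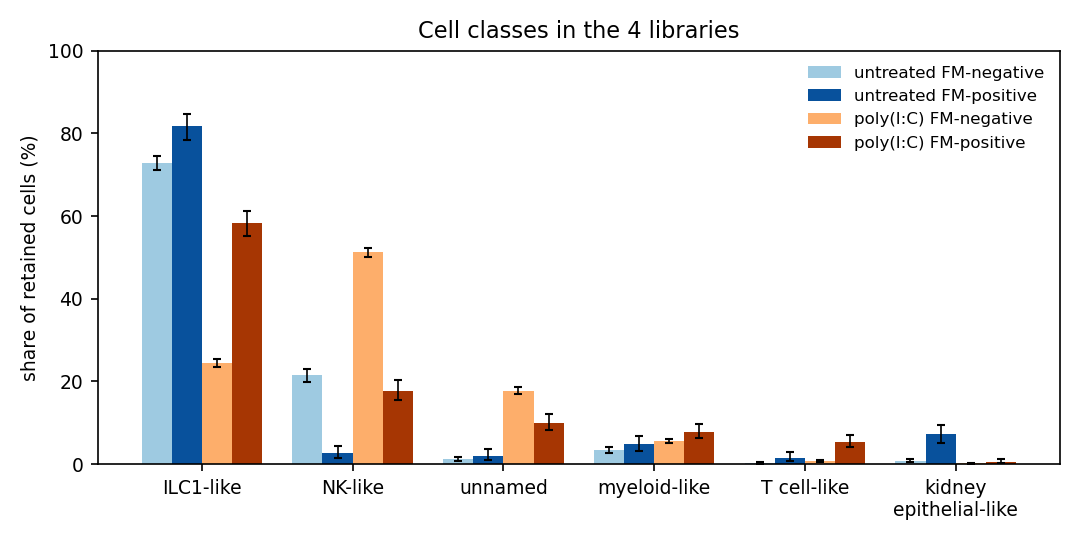
Share of retained cells (percent, vertical axis) in each class of cells for the 4 libraries, 1 library per group, with 95% Clopper-Pearson intervals for counting error only. NK-like cells reach 51.2% in the poly(I:C) FM-negative library and 2.74% in the untreated FM-positive library.

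Cells named for other classes were also found. T cell-like cells made up 0.307% (0.132 to 0.603), 1.54% (0.706 to 2.90), 0.716% (0.540 to 0.931) and 5.46% (4.13 to 7.06) of cells in the order untreated FM-negative, untreated FM-positive, poly(I:C) FM-negative and poly(I:C) FM-positive. Myeloid-like cells made up 3.41%, 4.79%, 5.61% and 7.89%, and kidney epithelial-like cells 0.767% (0.469 to 1.18), 7.18% (5.22 to 9.58), 0.182% (0.0996 to 0.305) and 0.607% (0.223 to 1.32). With at most 5% mitochondrial UMIs the kidney epithelial-like share was 0.347% in untreated FM-negative and 3.24% in untreated FM-positive, and with the treatments clustered apart 1.80% and 9.23%. With the treatments clustered apart, no untreated cluster was named T cell-like, and poly(I:C) FM-negative had 27 kidney epithelial-like cells against 14 in the main clustering. After thinning before clustering, 276 of 7549 poly(I:C) FM-negative cells were myeloid-like and 35 T cell-like. The main clustering had 431 and 55 of 7685. Ncr1 was found in 93.3% of the myeloid-like cells of untreated FM-negative and in 93.5% of those of poly(I:C) FM-negative, at 1285 and 891 CPM, against 1271 and 776 CPM in NK-like cells. Whether such cells are droplets with more than 1 cell was not tested. No cluster was named ILC2-like, ILC3-like, B cell-like, neutrophil-like, mast cell or basophil-like, endothelial-like or erythroid-like. Cluster 12, which stayed unnamed, came nearest to endothelial cells, with Rgs5, Ly6c1 and Tm4sf1 but also the tubule genes Umod and Slc12a3 among its leading genes. It held 0.115%, 1.37%, 0.130% and 0.202% of cells in the same order. Cells of these classes inside other clusters were not counted.

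The comparison of FM-positive with FM-negative cells asks how cells with a history of RORγt expression differ from those without. In untreated mice, the FM-positive library had lower levels of several genes of mature and circulating NK cells and higher levels of several ILC3-associated and kidney tubule genes. Klra4, an NK receptor gene (ENSMUSG00000079852, chromosome 6, 130043731 to 130067271, minus strand), stood at 14.5 CPM (10.7 to 19.3) against 115 CPM (109 to 121) in FM-negative cells. Gzma, the cytotoxic protease granzyme A (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981, minus strand), stood at 324 CPM (305 to 344) against 1843 CPM (1820.2 to 1866), 5.69-fold lower (5.35 to 6.06). Eomes, a transcription factor required for NK cell development (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132, plus strand), was at 27.2 CPM (21.8 to 33.5) against 129.5 CPM (124 to 136), 4.77-fold lower (3.85 to 5.98).

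In the NK maturation and circulation list, 0 of 19 measured members were at least 1.5-fold higher and 9 at least 1.5-fold lower (median log2 ratio -0.58, -2.11 to -0.13 over members, percentile 0). Its members Klra8, 29.6 against 169 CPM, 5.70-fold lower, the integrin gene Itgam (CD11b), 7.10 against 33.9 CPM, 4.77-fold lower, the L-selectin gene Sell, 35.5 against 110.1 CPM, 3.10-fold lower, and the tissue-exit receptor gene S1pr5, 6.17 against 24.9 CPM, 4.03-fold lower, were among the lowest genes of the library. So were Klra7, 23.5 against 103 CPM, 4.41-fold lower, Klra3, 24.7 against 67.8 CPM, 2.75-fold lower, the adaptor gene Sh2d1a, 9.88 against 61.2 CPM, 6.20-fold lower, Nrarp, 4.32 against 20.7 CPM, 4.78-fold lower, and Nr4a1, 19.4 against 53.1 CPM, 2.73-fold lower. For cytotoxic effector genes, 1 of 15 measured members were at least 1.5-fold higher and 4 at least 1.5-fold lower (median log2 ratio -0.20, -0.65 to -0.05 over members, percentile 0.0100). Gzmb (granzyme B) was at 236 against 372 CPM and the perforin gene Prf1 at 182 against 288 CPM. Of NK receptors, 1 of 20 members were higher and 4 lower by at least 1.5-fold (median log2 ratio -0.15, which became 0.04 over NK-like and ILC1-like cells only). The NK-like share of this FM-positive library was 2.74%, against 21.5% in the FM-negative library.

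Among ILC3-associated genes, 7 of 12 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 0.81, percentile 100). Rorc itself (ENSMUSG00000028150, chromosome 3, 94372794 to 94398276, plus strand) stood at 10.5 CPM (7.27 to 14.7) against 1.80 CPM (1.15 to 2.68), 5.82-fold higher (3.35 to 10.3), from 34 and 24 UMIs. A Rorc UMI was found in 3.42% of the FM-positive and 0.767% of the FM-negative cells, or 0.880% and 0.390% after thinning. It was also found in 9 of the 42 kidney epithelial-like cells of the FM-positive library (21.4%, median depth 6150.5 UMIs), and in 1 of the 560 NK-like cells of the FM-negative library (0.179%, median depth 4965.5 UMIs). The antioxidant gene Gpx1, on the same list, was at 945 against 246 CPM, with a log2 ratio of 1.93 that became 0.12 over NK-like and ILC1-like cells only. Lta, the cytokine lymphotoxin alpha, was at 29.3 against 9.69 CPM, 3.03-fold higher (2.30 to 3.98), and Tmem176a at 261 against 136 CPM.

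For tissue residency genes, 2 of 19 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 0.23, -0.01 to 0.36 over members, percentile 100), with the IL-7 receptor gene Il7r at 236 against 160.2 CPM and the creatine kinase gene Ckb at 305 against 203 CPM. The 12 highest genes were led by genes of the kidney proximal tubule. Miox, an inositol oxygenase (ENSMUSG00000022613, chromosome 15, 89334398 to 89337015, plus strand), was at 816 CPM (785 to 848) against 39.1 CPM (35.8 to 42.6). The fructose enzyme Aldob stood at 661 against 32.0 CPM, the extracellular peroxidase Gpx3 at 1075 against 69.2 CPM and the phosphate carrier Slc34a1 at 565 against 33.4 CPM. Akr1c21, Fxyd2, Hao2, Timp3, Keg1, Slc27a2, Igfbp7 and Spink1 completed them, between 15.9-fold and 24.8-fold higher. Kidney epithelial markers summed to 5851 against 532 CPM, beside kidney epithelial-like shares of 7.18% and 0.767%. The oxidative phosphorylation list had a median log2 ratio of 0.34 with 0 of 20 higher and 0 lower by at least 1.5-fold, which became 0.00 over NK-like and ILC1-like cells only.

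The other lists are given by their medians. The median log2 ratio was -0.11 for interferon-stimulated genes, -0.28 for cell cycle, -0.10 for cytokines and chemokines, -0.08 for cytokine receptors and feedback and 0.05 for inhibitory and activation receptors. It was -0.08 for immediate-early and heat-shock genes and 0.07 for glycolysis. MHC class I antigen presentation had -0.11, which turned to 0.05 over NK-like and ILC1-like cells only. Ly6a, 112 against 35.2 CPM, and Ifi27l2a, 64.5 against 38.8 CPM, also turned there, to log2 ratios of -0.43 and -1.13. Of the sex-linked genes only Xist and 1 other were measured, with Xist at 278 against 274 CPM. Cd3e, a T cell receptor component, was at 21.6 against 5.26 CPM. Without the T cell-like and other cells its log2 ratio was -0.31, from almost no UMIs. FM-negative cells then held 1 UMI in ILC1-like and 2 in NK-like cells, and FM-positive ILC1-like cells 0. That value therefore gives no direction.

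Within the ILC1-like class of untreated mice, which cluster 0 held for the most part in both libraries, FM-positive and FM-negative cells were close in most list medians. The median log2 ratio was 0.04 for interferon-stimulated genes, 0.04 for MHC class I antigen presentation, -0.05 for NK maturation and circulation, 0.02 for oxidative phosphorylation and 0.00 for cytotoxic effector genes. For ILC3-associated genes, 3 of 11 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 0.31, 0.10 to 1.53 over members, percentile 100). Rorc was at 9.28 CPM (5.88 to 13.9) against 1.92 CPM (1.14 to 3.03) from 23 and 18 UMIs, and Lta at 36.7 CPM (29.6 to 45.1) against 12.0 CPM (9.92 to 14.5). Rorc UMIs were found in 2.30% and 0.895% of these cells, or 0.633% and 0.424% after thinning, beside 21.4% of the kidney epithelial-like cells of the same FM-positive library. Eomes was 3.57-fold lower (2.12 to 6.50) at 6.05 against 21.6 CPM, Nr4a1 2.79-fold lower (2.02 to 3.96) at 16.1 against 45.1 CPM and Gzma 1.54-fold lower (1.42 to 1.67) at 279 against 431 CPM. Eomes and Gzma are NK markers used in naming. Eno1, a glycolytic enzyme, was 1.61-fold higher (1.48 to 1.75), and the interferon-stimulated kinase gene Cmpk2 2.21-fold higher (1.54 to 3.15). Only 16 untreated FM-positive cells were NK-like, so that class was not compared.

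After poly(I:C), most members of the tissue residency list were higher and most of the NK maturation and circulation list lower in the FM-positive than in the FM-negative library. Of the ILC1 markers, most of which are also on the tissue residency list, 9 of 10 members were higher and 0 lower by at least 1.5-fold. Pdcd1, the inhibitory receptor PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, minus strand), stood at 104 CPM (97.4 to 110.3) against 27.9 CPM (26.9 to 29.0), and the chemokine receptor gene Cxcr6 at 299 CPM (288 to 309.8) against 95.9 CPM (94.0 to 97.8). Cma1, a chymase gene among the NK markers used in naming, stood at 1.84 CPM (1.09 to 2.91) against 19.0 CPM (18.2 to 19.9), and the serpin gene Serpinb9b at 18.9 CPM (16.3 to 21.9) against 123 CPM (121 to 125). The NK-like share was 17.8% in the FM-positive and 51.2% in the FM-negative library, and cluster 3 held 8.59% and 14.6%.

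Among tissue residency genes, 12 of 20 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 0.98, 0.31 to 1.43 over members, percentile 100). They included Ckb, 149 against 50.4 CPM, 2.96-fold higher, the CD200 receptor gene Cd200r1, 84.4 against 30.6 CPM, 2.76-fold higher, and Zfp683 (Hobit), a transcription factor of resident lymphocytes, 126 against 47.0 CPM, 2.67-fold higher. For NK maturation and circulation, 2 of 18 measured members were at least 1.5-fold higher and 11 at least 1.5-fold lower (median log2 ratio -0.80, -1.39 to -0.32 over members, percentile 0). Among them were Klra4, 76.9 against 307 CPM, 3.99-fold lower, Klra8, 97.3 against 361 CPM, 3.71-fold lower, and Itgam, 39.0 against 116 CPM, 2.97-fold lower. Eomes, 58.6 against 155 CPM, 2.65-fold lower, and the inhibitory receptor gene Klrg1, 142 against 353 CPM, 2.49-fold lower, differed in the same direction. The secreted phosphoprotein gene Spp1 was at 309 against 1027 CPM, Sh2d1a at 56.8 against 155 CPM and Klra7 at 271 against 704 CPM. Of cytotoxic effector genes, 1 of 17 members were higher and 4 lower by at least 1.5-fold (median log2 ratio -0.25, -0.52 to 0.03 over members, percentile 0). Gzma was at 6924 against 14594 CPM, Prf1 at 419 against 990.2 CPM and Gzmk at 91.2 against 182 CPM, while the death ligand gene Tnfsf10 (TRAIL) was at 127 against 74.6 CPM.

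ILC3-associated genes again had a higher median, with 5 of 9 higher and 0 lower of the measured members by at least 1.5-fold (median log2 ratio 0.84, 0.10 to 1.70 over members, percentile 100). Tmem176a stood at 142 against 42.8 CPM and Tmem176b was 3.40-fold higher (3.26 to 3.55), both also ILC1 markers here. Rorc was low in both, at 0.511 CPM (0.166 to 1.19) against 0.0983 CPM (0.0471 to 0.181) from 5 and 10 UMIs, and it was found in 6 of the 14 kidney epithelial-like cells of the FM-negative library. Among cytokines and chemokines, 7 of 14 measured members were at least 1.5-fold higher and 1 at least 1.5-fold lower (median log2 ratio 0.47, -0.28 to 1.09 over members, percentile 100). The chemokine gene Xcl1 was at 2258 against 1198 CPM and lymphotoxin beta (Ltb) at 545 against 226 CPM. Cd3e was at 74.8 CPM (69.4 to 80.4) against 6.76 CPM (6.27 to 7.29), beside T cell-like shares of 5.46% and 0.716%. For interferon-stimulated genes, 6 of 42 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 0.29, 0.22 to 0.40 over members, percentile 100). Ifit3b was at 26.6 against 9.81 CPM, Ifit3 at 129 against 72.9 CPM and Slfn5 at 51.1 against 24.3 CPM.

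The remaining list medians after poly(I:C) were -0.14 for cell cycle, -0.16 for glycolysis, and 0.14 for cytokine receptors and feedback. They were 0.13 for NK receptors, 0.14 for inhibitory and activation receptors and -0.04 for oxidative phosphorylation. Without the clusters led by cell cycle genes, a setting chosen after seeing the data, the cell cycle median turned to 0.61 and that of oxidative phosphorylation to 0.02. Within ILC1-like cells, mostly of clusters 2 and 8 in both libraries, the interferon-stimulated median was 0.03, with 0 of 43 higher and 0 lower by at least 1.5-fold, and the cytotoxic median -0.05. The NK maturation and circulation list had 0 of 16 higher and 5 lower there (median log2 ratio -0.31, -1.25 to -0.01 over members, percentile 0). Its members Klra4, 0.856 CPM (0.233 to 2.19) against 13.4 CPM (11.7 to 15.3), Eomes, 5.14 CPM (3.29 to 7.64) against 19.1 CPM (17.0 to 21.3), and Sell, 6.21 CPM (4.16 to 8.91) against 16.2 CPM (14.3 to 18.3), all lay at low levels, and the first 2 are NK markers used in naming. Gzmc (granzyme C) was at 1928 against 1315 CPM.

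Within NK-like cells after poly(I:C), mostly of clusters 1, 4 and 5, the 176 FM-positive cells were compared with the 3936 FM-negative cells. The unnamed cluster 3, with 85 FM-positive and 1123 FM-negative cells, was not part of them. Its mean log2 level of NK over ILC1 markers was 2.73, against 2.69 in cluster 5. For NK maturation and circulation, 0 of 18 measured members were at least 1.5-fold higher and 8 at least 1.5-fold lower (median log2 ratio -0.55, -0.97 to -0.32 over members, percentile 0). For tissue residency, 8 of 18 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 0.49, 0.02 to 0.95 over members, percentile 100). Zfp683 was at 42.6 CPM (35.2 to 51.0) against 14.6 CPM (13.7 to 15.6) and the activating receptor gene Cd226 at 153 CPM (139 to 169) against 53.0 CPM (51.2 to 54.9). Prf1, an NK marker, was at 819 against 1212 CPM, Ltb at 171 against 89.5 CPM and Xcl1 at 1311 against 834 CPM. The cell cycle list had 15 of 30 higher and 0 lower by at least 1.5-fold (median log2 ratio 0.58), which turned to -0.14 without clusters 4 and 5. Those clusters held 55 and 57 of the 176 FM-positive and 1012 and 701 of the 3936 FM-negative NK-like cells. Cluster 1 held 60 of the FM-positive and 2126 of the FM-negative ones. Its leading genes included Sell, Itgam, S1pr5, Cma1, Klra4 and Klra8, all on the NK maturation and circulation list. Whether this mix of clusters underlies the medians of that list and of tissue residency was not tested.

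**Figure D2:**
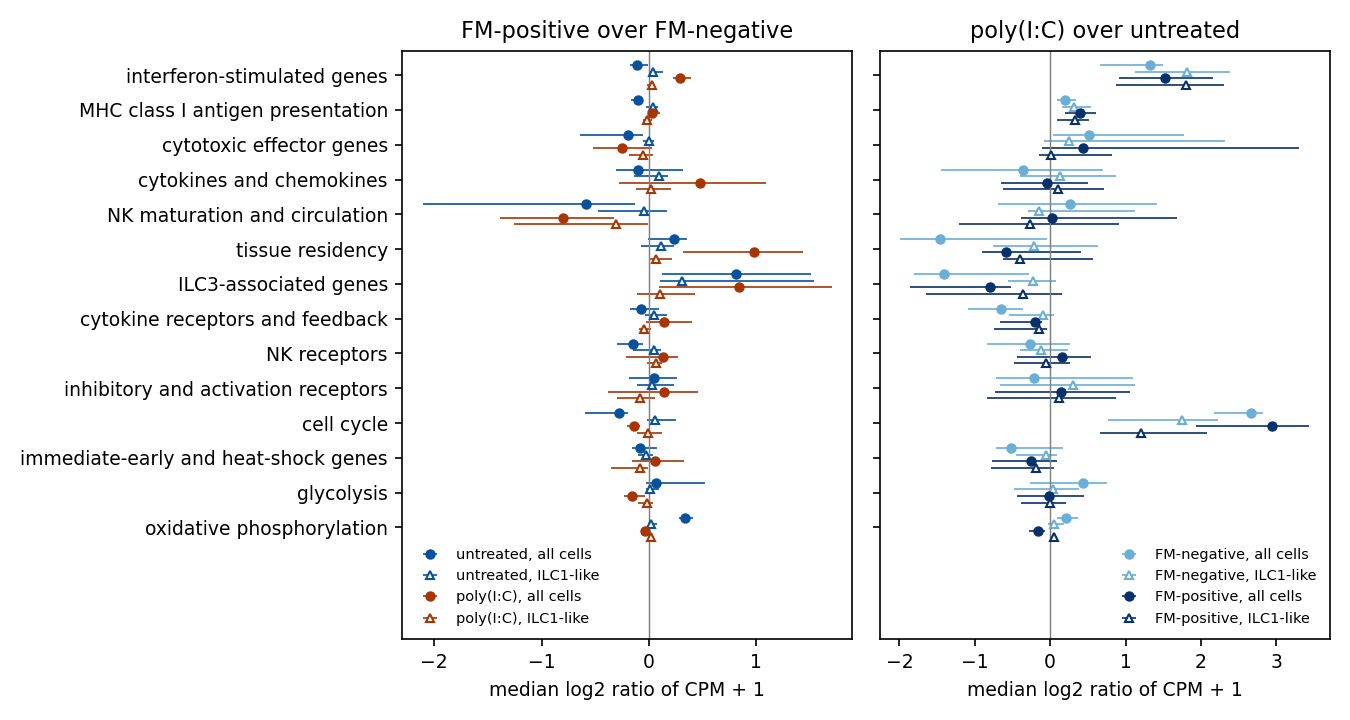
Median log2 ratio of each gene list (horizontal axis) in the comparisons of whole libraries and of ILC1-like cells, with 1 library per group and 95% binomial intervals over list members. Interferon-stimulated genes have a median of 1.32 after poly(I:C) in FM-negative libraries and of 0.04 between FM-positive and FM-negative ILC1-like cells of untreated mice.

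The comparison of poly(I:C) with untreated mice asks which transcripts differed after an interferon-inducing stimulus, in FM-negative and in FM-positive cells. In FM-negative cells, most members of the interferon-stimulated and cell cycle lists were higher, as were Gzma, Gzmb, Gzmc and Gzmk. Most members of the tissue residency list were lower. Of the ILC1 markers, most of which are also on that list, 0 of 10 members were higher and 8 lower by at least 1.5-fold. Ifi27l2a, an interferon-induced mitochondrial protein gene (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680, minus strand), stood at 2053 CPM (2044 to 2062) against 38.8 CPM (35.5 to 42.2), 53.0-fold higher (48.6 to 57.9). Ly6a (Sca-1), another interferon-stimulated gene, was at 1091 CPM (1085 to 1097) against 35.2 CPM (32.1 to 38.6). Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260, minus strand) was at 5117 CPM (5103 to 5131) against 372 CPM (362 to 383), 13.7-fold higher (13.4 to 14.1), and Gzma at 14594 CPM (14570.5 to 14617) against 1843 CPM (1820.2 to 1866), 7.92-fold higher (7.82 to 8.02). Il7r (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176, minus strand) was at 9.30 CPM (8.71 to 9.91) against 160.2 CPM (153 to 167), 17.2-fold lower (16.0 to 18.6).

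For interferon-stimulated genes in FM-negative cells, 29 of 42 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 1.32, percentile 100), and the median was 1.59 with median-of-ratios scaling. Slfn1 was at 40.3 against 1.20 CPM and the RNA exonuclease gene Isg20 at 169 against 28.4 CPM. All 30 members of the cell cycle list were at least 1.5-fold higher (median log2 ratio 2.67, or 2.85 relative to all genes, percentile 100). The proliferation marker Mki67 was at 192 against 20.4 CPM, Birc5 at 106 against 8.64 CPM, Ube2c at 86.8 against 6.46 CPM, Tk1 at 89.2 against 8.34 CPM and Pclaf, a replication factor outside the list, at 215 against 20.3 CPM. Without clusters 4 and 5 the cell cycle median was 1.86. Of cytotoxic effector genes, 8 of 17 members were higher and 1 lower by at least 1.5-fold (median log2 ratio 0.51, or 0.69 relative to all genes, percentile 100). Gzmk was at 182 against 2.85 CPM and Gzmc at 893 against 206 CPM. For MHC class I antigen presentation, 4 of 20 members were higher and 0 lower (median log2 ratio 0.20, or 0.38 relative to all genes, percentile 96.2). The peptide transporter gene Tap1 was at 295 against 162 CPM and H2-T22 at 549 against 311 CPM.

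Of tissue residency genes, 2 of 18 members were higher and 12 lower by at least 1.5-fold (median log2 ratio -1.46, or -1.28 relative to all genes, percentile 0). Cxcr6 was at 95.9 against 465 CPM, Ckb at 50.4 against 203 CPM and Rora at 9.35 against 70.9 CPM. ILC3-associated genes also had a lower median, with 0 of 9 higher and 6 lower (median log2 ratio -1.41, or -1.23 relative to all genes, percentile 0), and the stem cell factor receptor gene Kit at 8.67 against 36.6 CPM. ILC1-like cells made up 24.6% of this poly(I:C) library against 72.8% of the untreated one, and NK-like cells 51.2% against 21.5%. Spp1, 1027 against 19.2 CPM, Klrg1, 353 against 23.7 CPM, Plac8, 425 against 34.8 CPM, and Ly6c2, 1673 against 369 CPM, were higher. Emb, 17.7 against 181 CPM, Krt83, 4.43 against 64.5 CPM, Phkg1, 5.21 against 58.1 CPM, and the MHC class II gene H2-Aa, 20.6 against 174 CPM, were lower. H2-Aa is among the leading genes of the myeloid-like cluster, and 2101 of its 2312 UMIs in the untreated library lay in 89 myeloid-like cells. The NK maturation and circulation list went both ways, with 7 of 19 higher and 5 lower (median 0.26, or 0.44 relative to all genes).

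Cytokine and receptor genes also differed in FM-negative cells. For cytokine receptors and feedback, 2 of 22 members were higher and 12 lower by at least 1.5-fold (median log2 ratio -0.65, or -0.47 relative to all genes, percentile 0). The IL-18 receptor gene Il18r1 was at 17.7 against 129 CPM, its partner Il18rap at 51.5 against 131 CPM and the IL-12 receptor gene Il12rb1 at 84.4 against 36.5 CPM. Among cytokines and chemokines, 3 of 14 members were higher and 6 lower (median -0.36, or -0.18 relative to all genes), with Ccl5 at 10042 against 4745 CPM, Ltb at 226 against 795 CPM, Xcl1 at 1198 against 2478 CPM and Il2 at 1.73 against 13.8 CPM. The inhibitory receptor genes Havcr2 (TIM-3), 22.7 against 0.676 CPM, and Tigit, 274 against 90.4 CPM, were higher. So was Entpd1 (CD39), 117 against 41.7 CPM. Their list, inhibitory and activation receptors, had 5 of 15 higher and 5 lower (median -0.21, or -0.03 relative to all genes). NK receptors had 5 of 21 higher and 8 lower (median -0.26, or -0.08 relative to all genes), with Klra7 at 704 against 103 CPM. Immediate-early and heat-shock genes had 1 of 18 higher and 8 lower (median log2 ratio -0.52, or -0.34 relative to all genes, percentile 0.0300). Junb was at 1276 against 2095 CPM and Hspa1b at 3.43 against 19.0 CPM. Glycolysis had 6 of 15 higher and 2 lower (median log2 ratio 0.44, or 0.62 relative to all genes, percentile 100), with the lactate dehydrogenase gene Ldha at 852 against 489.8 CPM. Oxidative phosphorylation had a median of 0.22, or 0.40 relative to all genes. Xist was at 247 against 274 CPM, a log2 ratio that turned to 0.13 with median-of-ratios scaling.

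In FM-positive cells, most members of the interferon-stimulated and cell cycle lists were also higher, while the glycolysis median stood at -0.02 against 0.44 in FM-negative cells. Ifi27l2a stood at 2459.7 CPM (2429 to 2491) against 64.5 CPM (56.1 to 73.9), 38.1-fold higher (33.3 to 43.9), Gzmb at 3802 CPM (3764 to 3841) against 236 CPM (219 to 253), 16.1-fold higher (15.0 to 17.3), and Gzma at 6924 CPM (6872 to 6976) against 324 CPM (305 to 344), 21.4-fold higher (20.1 to 22.7). For interferon-stimulated genes, 33 of 42 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 1.52, or 1.72 relative to all genes, percentile 100). Ly6a was at 1042 against 112 CPM and Isg20 at 198 against 18.2 CPM. All 30 cell cycle genes were again at least 1.5-fold higher (median log2 ratio 2.94, or 3.15 relative to all genes, percentile 100). Tk1 was at 90.5 against 4.01 CPM, Top2a at 195 against 14.5 CPM and Ccna2 at 59.3 against 2.78 CPM. The median was 1.93 without clusters 4 and 5. Of MHC class I genes, 6 of 20 members were higher and 0 lower (median log2 ratio 0.40, or 0.60 relative to all genes, percentile 100). Cytotoxic effector genes had 8 of 16 higher and 1 lower (median log2 ratio 0.44, or 0.64 relative to all genes, percentile 100), with Gzmc at 1303 against 131 CPM. Gzmk stood at 91.2 against 0.926 CPM, from 3 UMIs in untreated cells, 98.5-fold higher (33.6 to 479).

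Tissue residency genes had 4 of 20 higher and 10 lower in FM-positive cells (median log2 ratio -0.58, or -0.38 relative to all genes, percentile 0.0100). Il7r was at 28.1 against 236 CPM and Rora at 22.7 against 90.7 CPM. ILC3-associated genes had 0 of 12 higher and 9 lower (median log2 ratio -0.80, or -0.60 relative to all genes, percentile 0.450). Rorc was at 0.511 against 10.5 CPM, Gpx1 at 244 against 945 CPM and Kit at 11.6 against 29.3 CPM. The lowest genes were those of the proximal tubule, Pck1, 3.17 against 348 CPM, Miox, 24.7 against 816 CPM, Aldob, 26.1 against 661 CPM, and Slc34a1, 21.9 against 565 CPM, beside kidney epithelial-like shares of 0.607% after poly(I:C) and 7.18% without. Higher genes included Pclaf, 212 against 12.7 CPM, Plac8, 251 against 21.3 CPM, Klrg1, 142 against 8.95 CPM, Ly6c2, 2697 against 354 CPM, Klra7, 271 against 23.5 CPM, and Klra1, 131 against 8.33 CPM. Il18r1 was at 16.4 against 110.2 CPM, the interferon gamma receptor gene Ifngr1 at 411 against 819 CPM, Ccl5 at 8294 against 3368 CPM, Ccl3 at 953 against 378 CPM and Nr4a1 at 67.6 against 19.4 CPM.

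The other medians in FM-positive cells were 0.03 for NK maturation and circulation, 0.15 for NK receptors and 0.14 for inhibitory and activation receptors, or 0.23, 0.36 and 0.34 relative to all genes. They were -0.04 for cytokines and chemokines, -0.25 for immediate-early and heat-shock genes and -0.02 for glycolysis, or 0.16, -0.05 and 0.18 relative to all genes, so that the sign turned for the first and the last. Those of cytokine receptors and feedback, -0.20, and of oxidative phosphorylation, -0.16, turned to 0.10 and 0.15 with median-of-ratios scaling, and were 0.00 and 0.04 relative to all genes.

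Within ILC1-like cells, most members of the interferon-stimulated list and the granzyme genes Gzma, Gzmb and Gzmc were higher after poly(I:C) in both FM-negative and FM-positive cells. These cells were mostly of cluster 0 in untreated mice and of clusters 2 and 8 after poly(I:C). Cluster 8, led by Ccl1 and Crtam, held 279 of the 1887 FM-negative and 72 of the 576 FM-positive cells after poly(I:C). Its name depends on the processing. A cluster led by the same 2 genes was named NK-like after thinning, and among poly(I:C) cells when the treatments were clustered apart. For interferon-stimulated genes in FM-negative cells, 36 of 43 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 1.82, or 1.95 relative to all genes, percentile 100). In FM-positive cells there were 34 of 42 higher and 0 lower (median log2 ratio 1.80, or 1.99 relative to all genes, percentile 100). Ifi27l2a stood at 2331 CPM (2307 to 2354) against 25.9 CPM (22.7 to 29.4) in FM-negative and at 2444 CPM (2399 to 2489) against 14.5 CPM (10.2 to 20.1) in FM-positive cells, with Ly6a at 998 against 23.3 CPM and 987 against 23.4 CPM. Slfn1 was at 62.5 CPM (58.7 to 66.5) against 0.533 CPM (0.173 to 1.24) in FM-negative cells, and in FM-positive cells at 53.7 against 0 CPM, at least 44.4-fold higher against the floor of 3 counts. The ISG15 protease gene Usp18 was at 171 against 16.0 CPM in FM-negative and Isg20 was 9.20-fold higher (7.04 to 12.2) in FM-positive cells.

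Gzma, Gzmb and Gzmc in ILC1-like cells stood above their untreated level, while the cytotoxic list that holds them had medians of 0.25 in FM-negative and 0.01 in FM-positive cells, or 0.38 and 0.20 relative to all genes. Gzmb was at 3476 CPM (3447 to 3505) against 264 CPM (254 to 275) in FM-negative cells, 13.2-fold higher (12.6 to 13.7), and at 3056 CPM (3006 to 3107) against 273 CPM (253 to 294) in FM-positive cells, 11.2-fold higher (10.4 to 12.1). Gzma, one of the NK markers, was at 2546 CPM (2522 to 2571) against 431 CPM (418 to 444), 5.91-fold higher (5.72 to 6.11), and at 2037 CPM (1996 to 2078) against 279 CPM (259 to 301), 7.30-fold higher (6.75 to 7.89), while NK-like cells of the same poly(I:C) libraries had 17389.5 and 14115 CPM. Gzmc was at 1315 against 263 CPM and 1928 against 169 CPM. Prf1 differed less, with 246 against 207 CPM in FM-negative and 204 against 207 CPM in FM-positive cells.

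Other genes of ILC1-like cells differed in the same direction in FM-negative and FM-positive cells. Ly6c2 was at 3457 against 431 CPM and 3437 against 360.4 CPM, the chemokine gene Ccl3 at 1119.8 against 491 CPM and 1130.2 against 392 CPM, and Tigit at 185 against 84.0 CPM and 172 against 74.3 CPM. The cytokine-induced feedback gene Cish was at 259.5 against 108 CPM and 254 against 131 CPM. Lower were Il18r1, 24.6 against 118 CPM and 21.2 against 126 CPM, Ifngr1, 465 against 857 CPM and 465 against 951 CPM, and Il2, 5.85 against 17.8 CPM and 9.42 against 26.6 CPM. Hspa1b, a heat-shock gene induced by tissue handling, was 8.37-fold lower (6.03 to 11.9) and 7.27-fold lower (3.98 to 14.2). The cell cycle list had 19 of 24 higher and 0 lower (median log2 ratio 1.74, or 1.87 relative to all genes, percentile 100) and 17 of 22 higher and 0 lower (median log2 ratio 1.20, or 1.39 relative to all genes, percentile 100). Mki67 was at 37.7 against 4.05 CPM and 37.5 against 3.23 CPM. MHC class I antigen presentation had medians of 0.32 and 0.33, or 0.45 and 0.52 relative to all genes, with H2-T22 at 676 against 321 CPM and 669 against 331 CPM.

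**Figure D3:**
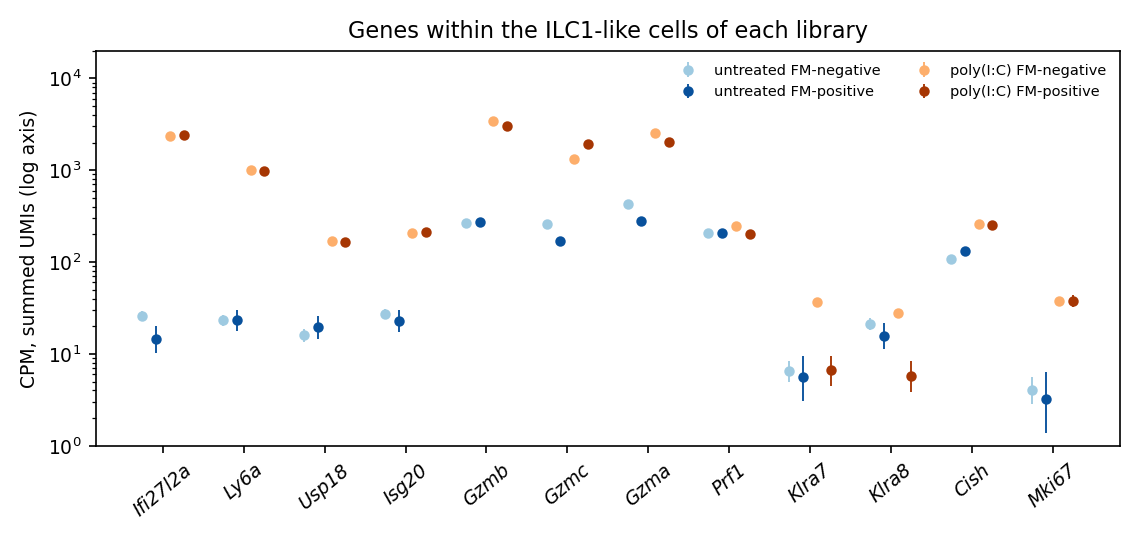
Level of named genes (CPM, logarithmic axis) in ILC1-like cells of the 4 libraries, 1 library per group, with exact Poisson 95% intervals for counting error only. Gzmb lies at 264 and 273 CPM in the untreated and at 3476 and 3056 CPM in the poly(I:C) libraries.

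Within FM-negative NK-like cells, mostly of cluster 6 in untreated mice and of clusters 1, 4 and 5 after poly(I:C), Gzma, Gzmb and the members of the cell cycle list were higher after poly(I:C). Gzmb was at 5654 CPM (5635 to 5673) against 772 CPM (742 to 804), 7.32-fold higher (7.03 to 7.62), and Gzma, an NK marker, at 17389.5 CPM (17357 to 17422) against 6365 CPM (6276 to 6455), 2.73-fold higher (2.69 to 2.77). Of cytotoxic effector genes, 9 of 17 members were higher and 1 lower (median log2 ratio 0.63, or 0.75 relative to all genes, percentile 100). For interferon-stimulated genes, 20 of 41 measured members were at least 1.5-fold higher and 1 at least 1.5-fold lower (median log2 ratio 0.55, or 0.66 relative to all genes, percentile 100). Ifi27l2a was at 1803 against 50.2 CPM and Ly6a at 1105 against 55.7 CPM. Inhibitory and activation receptors had 8 of 14 higher and 2 lower (median log2 ratio 1.02, or 1.14 relative to all genes, percentile 100). Lag3 was at 99.1 against 11.7 CPM and Havcr2 at 26.0 against 0 CPM, at least 26.6-fold higher against the floor of 3 counts. The cell cycle list had 30 of 30 higher and 0 lower (median log2 ratio 1.65, or 1.77 relative to all genes, percentile 100), a median that was 0.37 without clusters 4 and 5. Klrg1 was at 422 against 73.6 CPM, Il18rap at 50.1 against 151 CPM, Ltb at 89.5 against 441 CPM and Cd226 at 53.0 against 116 CPM.

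The poly(I:C) differences of FM-positive and FM-negative cells were set against each other gene by gene. Across 7060 genes of whole libraries, Pearson's r was 0.78 and Spearman's rho 0.80. Across 6611 genes of ILC1-like cells they were 0.88 and 0.78. These are correlations across genes, which are not independent replicates. FM-positive and FM-negative cells of a treatment came from the same mice, so the 2 sets of ratios share animals. In ILC1-like cells the median difference of the log2 ratios, FM-positive minus FM-negative, was -0.02 (-0.10 to 0.06 over 43 members) for interferon-stimulated genes, -0.03 (-0.10 to 0.03) for MHC class I antigen presentation and -0.06 (-0.23 to 0.11) for cytotoxic effector genes. Over whole libraries it was 0.44 (0.32 to 0.48) for interferon-stimulated genes and 0.64 (0.45 to 0.94) for tissue residency. For glycolysis it was -0.35 (-0.58 to -0.07), for oxidative phosphorylation -0.38 (-0.46 to -0.31) and for cytokine receptors and feedback 0.25 (0.12 to 0.31). In ILC1-like cells these were -0.02 (-0.11 to -0.01) for tissue residency, -0.09 (-0.19 to 0.02) for glycolysis, 0.02 (-0.05 to 0.05) for oxidative phosphorylation and -0.11 (-0.24 to 0.00) for cytokine receptors and feedback. With 1 library per group, these differences were not tested.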

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

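The tests of 6 other NK transcripts for Gzma and Gzmb were chosen after the values were seen, while the other tests of this part were set before.

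In 2 gene lists of at least 5 members the medians had opposite signs in the 2 groups of a contrast, with both 95% intervals over members away from 0. Other lists of that size had opposite signs with an interval that held 0. Interferon-stimulated genes had a median log2 ratio of FM-positive against FM-negative of -0.11 in untreated and 0.29 in poly(I:C) libraries, but of 0.04 and 0.03 within ILC1-like cells. Oxidative phosphorylation genes had a median log2 ratio of poly(I:C) against untreated of -0.16 in FM-positive and 0.22 in FM-negative cells, and of FM-positive against FM-negative of 0.34 in untreated and -0.042 in poly(I:C) libraries. These signs depend on the processing, since the -0.16 turned to 0.15 with median-of-ratios scaling and to 0.17 over NK-like and ILC1-like cells only, the 0.34 became 0.00 over those cells, and the -0.042 turned to 0.021 without clusters 4 and 5. These differences between groups were not tested, since each group is 1 library.

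Cells named for classes other than NK cells and ILC1 were found, and whether they are droplets with more than 1 cell was not tested. In the order untreated FM-negative, untreated FM-positive, poly(I:C) FM-negative and poly(I:C) FM-positive, T cell-like cells made up 0.307%, 1.54%, 0.716% and 5.46%. Myeloid-like cells made up 3.41%, 4.79%, 5.61% and 7.89%, and kidney epithelial-like cells 0.767%, 7.18%, 0.182% and 0.607%, in the same order. With at most 5% mitochondrial UMIs the 7.18% became 3.24%. In the barcodes left out by the filter, kidney epithelial markers held 2.43%, 1.96%, 0.473% and 3.01% of UMIs, against 0.0532%, 0.585%, 0.0233% and 0.0370% in retained cells.

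Interferon-stimulated genes were higher after poly(I:C), with a median log2 ratio of 1.32 in FM-negative libraries. Depth as the cause cannot be decided by the median of 1.43 after every cell was thinned to 2000 UMIs. CPM of summed UMIs already scales each library to the same total, so thinning could hardly change it. A different mix of classes as the whole cause is argued against by 1.82 within ILC1-like cells, and myeloid or kidney cells by 1.26 over NK-like and ILC1-like cells only. Within NK-like cells the median was 0.55, and both classes lie in other clusters after poly(I:C) than before (0 against 2 and 8 for ILC1-like cells), so that a different mix of subsets within a class stays open. A response to poly(I:C) is a hypothesis, and with 1 library per group differences between mice or preparations cannot be told apart from it.

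The NK maturation and circulation list had a median log2 ratio of -0.58 in the FM-positive against the FM-negative library of untreated mice, with 9 of 19 members at least 1.5-fold lower and 10 within 1.5-fold. RNA of kidney cells as the cause is argued against by a median of -0.88 over the same members in NK-like and ILC1-like cells only. A different mix of classes predicts a small difference within each class. In untreated mice, where only ILC1-like cells could be compared, the median was -0.045. Its members were chosen anew by their level in that class, so they are not the same set as behind the -0.58. After poly(I:C) the medians within classes were -0.31 in ILC1-like and -0.55 in NK-like cells, against -0.80 in whole libraries, so that the mix of these classes leaves part of the difference open there. Within NK-like cells, cluster 1 held 60 of 176 FM-positive and 2126 of 3936 FM-negative cells. A different mix of subsets within that class thus also stays open. Some members, among them Eomes, Itgam and Klra4, were used in naming the classes, and whether the smaller NK-like share comes from the fate-mapped cells or from the sort was not tested.

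Gzma and Gzmb were higher in ILC1-like cells after poly(I:C), and NK-like cells hold more of both. If free RNA or NK cells mixed into the class were the source of Gzma, 6 other NK transcripts would have to be higher by the same share of the NK-like level, but their median share was 0.303 of that needed. This value lay between the bounds set first, 0.25 and 0.5, and the count then set against mixing, 5 of 6 transcripts with their upper counting limit below the level needed, was added after seeing it. Klra4, Klra8 and Prf1 are NK markers used in naming, and Klra4 and Klra8 lead cluster 1. Clustering can thus keep cells with them out of the ILC1-like class, so low shares say little on mixed NK cells. Ccl5 was already at 4042 CPM in untreated FM-negative ILC1-like cells, and its share was 70.0%. The shares also assume that the untreated levels did not change. For Gzmb the median was 0.0635, again with 5 of 6 transcripts below, and Gzma in FM-positive relative to FM-negative ILC1-like cells was 0.80 despite NK-like shares of 17.8% and 51.2%, which argues against free RNA that follows the NK cells of a library. In FM-positive cells, looked at after these values, Klra4, Klra8, Klra7, Klrg1, Prf1 and Ccl5 gave shares of 0.439%, -5.42%, 0.201%, 2.43%, -0.365% and 87.5% against 12.7% for Gzma, with the same limits. In FM-negative cells the 0.303 leaves open that mixed cells hold part of the difference, and a higher level in the ILC1-like cells themselves is a hypothesis.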

How the results depend on the processing

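Settings that left out clusters 4 and 5, counted cluster 3 as NK-like, removed the highest doublet scores, or for class shares dropped the cell filter and doublet removal together, were chosen after seeing the data. No paired analysis was possible because each group was 1 library and the labels number no mice. Of 1008 list medians under the alternatives, 941 stayed within their interval, 58 moved beyond it and 9 changed sign. Of 3865 values of named genes, 2842 stayed, 1009 moved and 14 changed sign, and of 220 class shares 150 stayed and 70 moved. Where no cause is given below, the cause was not tested. The untreated FM-positive library, with 585 cells and 3239785 UMIs, limits the precision of each comparison that it enters.

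For shares of cells, thinning before clustering gave 70.3% ILC1-like and 25.1% NK-like cells in untreated FM-negative, and NK-like shares of 7.04% in untreated FM-positive, 71.2% in poly(I:C) FM-negative and 33.9% in poly(I:C) FM-positive. The thinned NK-like cells included a cluster led by Ccl1 and Crtam, with 92, 20, 204 and 37 cells in the same order. Cluster 8 of the main clustering, led by the same 2 genes, was ILC1-like. With no cell filter but doublets removed among the cells that pass it, ILC1-like shares were 70.2%, 70.5%, 22.7% and 54.0% in untreated FM-negative, untreated FM-positive, poly(I:C) FM-negative and poly(I:C) FM-positive, and the NK-like share of poly(I:C) FM-negative was 48.1%. With no cell filter and no doublet removal, NK-like shares were 19.6% in untreated FM-negative, 40.6% in poly(I:C) FM-negative and 14.2% in poly(I:C) FM-positive, and the ILC1-like share of untreated FM-positive was 71.5%. At most 5% mitochondrial UMIs gave 86.5% ILC1-like cells in untreated FM-positive and 52.4% NK-like cells in poly(I:C) FM-negative.

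Leiden resolutions of 0.3 and 1 gave NK-like shares of 66.2% and 54.8% in poly(I:C) FM-negative, and 0.3 gave 27.2% in poly(I:C) FM-positive. Keeping doublets gave 22.7% ILC1-like and 48.7% NK-like cells in poly(I:C) FM-negative and 54.3% ILC1-like cells in poly(I:C) FM-positive, although 0 cells had been removed from the former, since the clusters were built anew. Keeping treatment-responsive genes gave ILC1-like shares of 22.9% and 54.6% and NK-like shares of 68.1% and 31.5% in poly(I:C) FM-negative and FM-positive. Treatments clustered apart gave 21.3% and 51.6% ILC1-like and 57.1% and 25.1% NK-like cells. Counting cluster 3 as NK-like gave 65.8% and 26.4%, in the same order. In the comparisons within NK-like cells it moved 33 values of named genes beyond their interval while 92 stayed, and 1 list median while 27 stayed.

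Over NK-like and ILC1-like cells only, the untreated comparison of FM-positive with FM-negative gave medians of 0.049 for MHC class I antigen presentation and 0.044 for NK receptors, both with the sign changed, and 0.39 for tissue residency. Log2 ratios with the sign changed were -0.43 for Ly6a, -1.13 for Ifi27l2a, -0.036 for Tpi1, -0.024 for Ndufb8, -0.037 for Atp5b, 0.13 for Ncr1, 0.085 for Klrb1c and -0.31 for Cd3e. That of Cd3e rests on almost no UMIs and gives no direction. The NK maturation median was -1.11 there with members chosen anew by level, and -0.88 over the members of the whole libraries. After poly(I:C), Atf3 changed to -0.82 over these cells, Klrb1c to -0.016 with median-of-ratios scaling, and the medians of cell cycle and oxidative phosphorylation to 0.61 and 0.021 without clusters 4 and 5. In NK-like cells the cell cycle median changed to -0.14 without these clusters.

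For poly(I:C) against untreated in FM-negative, median-of-ratios scaling gave 1.59 for interferon-stimulated genes, 0.48 for MHC class I antigen presentation, 2.93 for cell cycle and, with the sign changed, 0.13 for Xist. The cell cycle median was 2.88 with equal weight per cell, 2.88 over NK-like and ILC1-like cells only, 2.05 with a pseudocount of 5 CPM and 1.86 without clusters 4 and 5. In FM-positive, median-of-ratios scaling gave 0.71 for MHC class I antigen presentation and, with the sign changed, 0.10 for cytokine receptors and feedback, 0.15 for oxidative phosphorylation and 0.16 for Klrb1c. The cell cycle median was 1.93 without clusters 4 and 5. Over NK-like and ILC1-like cells, oxidative phosphorylation changed to 0.17, Atp5b to 0.25 and Ptprc to -0.13. In ILC1-like FM-positive cells, cytokine receptors and feedback changed to 0.084 with median-of-ratios scaling.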

Other observations

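The genes of this part were chosen after seeing the data. UMIs of T cell receptor constant genes in T cell-like cells of the 2 poly(I:C) libraries are given beside those in NK-like cells of the same libraries as background, FM-negative first. Trdc, the delta chain, was found in 74.5% of 55 and 0% of 54 T cell-like cells, against 22.1% and 19.3% of NK-like cells. Trac, the alpha chain, was found in 36.4% and 79.6%, against 22.5% and 27.3%. The gamma chain genes Tcrg-C1, in 50.9% and 11.1%, and Tcrg-C2, in 60.0% and 35.2%, were found in at most 1.70% of NK-like cells. Trbc2, a beta chain gene, was found in 85.5% and 81.5%, against 61.4% and 58.5%. These differences between 2 libraries were not tested. Ncr1 was found in 94.5% and 96.3% of these cells, against 99.0% and 98.3% of NK-like cells, and mixed droplets were not tested. Median depth was 13338 UMIs in the FM-negative and 9123.5 UMIs in the FM-positive T cell-like cells.

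Transcripts of the CD3 complex were not all absent from cells sorted as CD3-negative. In cluster 3, Cd3g stood at 772 CPM and Cd3d at 187 CPM, but Cd3e at 0.0639 CPM, against 1325 CPM, 869 CPM and 925 CPM in the T cell-like cluster 10. ILC1-like cells had Cd3g at 71.9 and 51.7 CPM in untreated FM-negative and FM-positive and at 184 and 133 CPM after poly(I:C), with Cd3e at or below 0.370 CPM. Gzma in the unnamed cells, most of them of cluster 3, stood at 17509.7 CPM in poly(I:C) FM-negative, against 17389.5 CPM in NK-like cells.

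Myeloid-like cells carried NK cell transcripts beside their own. In the poly(I:C) FM-negative library they had Ncr1 at 891 CPM, Gzma at 12413 CPM and the complement gene C1qa at 707 CPM, while NK-like cells had C1qa at 3.36 CPM. In untreated FM-negative they had Ncr1 at 1285 CPM and C1qa at 844 CPM. Their median UMIs were 1.16 and 1.11 times those of their libraries. Kidney epithelial-like cells of untreated FM-positive had Ncr1 at 18.9 CPM. Whether the myeloid-like cells are droplets with more than 1 cell was not tested.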
